A study of Homo sapiens with 2 samples.

How the data were processed

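Gene expression was measured on 2 Affymetrix whole-transcript arrays, one hybridised with RNA from A549 cells transfected with a control siRNA (siCONTROL) and one with RNA from A549 cells transfected with an siRNA against p62/SQSTM1 (siP62). A549 is an established human lung adenocarcinoma cell line. An siRNA is a short double-stranded RNA that directs the degradation of a matching mRNA. Total RNA was extracted with Trizol at 24 hours, and biotinylated double-stranded cDNA was made from 100 ng of it, per the labels' protocols and the series' design text. Each group held 1 array, so there was no replicate and no spread within a group.

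The deposited table held 1 log2 value per probe set and array for 48226 probe sets, written to 2 decimals. RMA and Transcriptome Analysis Console 4.0.2.15 are named in the submitters' processing notes. As commonly defined, RMA corrects the background, makes the distributions of the arrays alike by quantile normalization and summarises the probes of a probe set as a log2 value; which arrays entered that step is not given in the sources used here. The log2 scale was taken from these notes and from the values, which ran from 1.16 to 13.75 in the siCONTROL array and from 1.32 to 13.75 in the siP62 array with medians of 4.07 and 4.02. Where the distributions were made alike, a shift of all genes in one direction would not be seen, and differences are relative to the bulk of the probe sets. The genome build and annotation behind the probe sets are not given in the sources used here, so no coordinates are printed. Scanner files were not used here. No detection call came with the values, and the number of arrays limits the precision.

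Genes were named from the platform annotation supplied for the probe sets. It gave 1 gene symbol for 16098 probe sets and several for 0; the other 32128 were unnamed here and entered no comparison. All 16098 gene identifiers matched the RefSeq gene table of GRCh38.p14, which was used for names alone and to update 10 older symbols in the gene lists. The named probe sets covered 14884 genes, 779 of them with more than 1 probe set; the probe set with the highest mean of the 2 arrays stood for the gene. A gene was kept if the higher of its 2 values was at or above 5.35, the median over both arrays and all named probe sets. This left 7896 genes (53.1%). The difference of a gene is its siP62 value minus its siCONTROL value on the log2 scale.

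With 1 array per group no test between the groups was possible and no p-value is given. Genes were counted at a difference of 2-fold or more, and a gene's difference was set beside the robust SD (scaled median absolute deviation) of the differences in its bin, 1 of 20 bins of genes of like mean level. That SD describes the spread over genes between these 2 arrays and is not an error between replicates. For each of 40 gene lists fixed before the data were examined, the median difference of the kept members was placed among the medians of 10000 random lists of the same size, drawn from the same 20 bins. A list of at least 5 kept members is said to stand apart below percentile 2.5 or above percentile 97.5. Of the 967 genes in the lists, 568 were named on the array and 431 were kept.

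The genes named in the text were chosen by a rule of size fixed before the data were examined. They are SQSTM1; the 12 kept genes with the highest and the 12 with the lowest difference, leaving out SQSTM1 and symbols of uncharacterised loci, microRNAs, small RNAs and olfactory receptors; up to 4 members of each list standing apart, those with the largest difference in the list's direction; the 4 members with the largest absolute difference in the lists of NRF2 targets, NF-kB targets, autophagy receptors and p62 partners, and interferon-stimulated genes; and control genes, of which 5 of 7 were named on the array. Other members are named to illustrate a list and were chosen after their values were seen.

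The procedure was tested on simulated data built on the mean levels of the real genes. Of 200 genes changed by 1.5 on the log2 scale, with a spread of 0.2, 93.0% were counted as 2-fold changed, and of 200 changed by 2.5, 97.5% were. In either case 0 unchanged genes were counted, which was near certain with normal noise of that spread at every level. The robust SD of the real differences ranged from 0.15 to 0.39 over the level bins. The 0 therefore does not show that real genes past 2-fold are beyond noise. Of 620 list scores without any change, 38 (6.1%) stood apart. The noise was drawn independently for each gene, so a share close to that of random lists was set in advance. It does not cover lists whose members vary together between arrays. Of the 31 lists that could be scored, 32.3% stood apart after all members were shifted by 0.15 and 87.1% after a shift of 0.3, with a spread of 0.25 between genes.

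The alternatives fixed before the data were examined were subtraction of the median difference, subtraction of a loess curve of difference on mean level, quantile normalization of the deposited columns, the mean over a gene's probe sets, no filter on low values, a filter at the 70th percentile, a threshold of 1.5-fold, 5 level bins in place of 20, and the mean in place of the list median. Random lists drawn from genes with mRNA accessions alone, and the mean and the 5 bins applied to each single list rather than to the number of lists, were added after the data were seen. In the first of these, list members without an mRNA accession were left out as well. The random draw of the lists was changed once after the first results had been seen, so that a list had the same draw in every step. Both draws are used here: the same 3 lists stood apart in each, and percentiles close to 2.5 or 97.5 moved across the limits with the draw. With no replicates, a gene's difference counted as moved under an alternative when it shifted by more than the robust SD of its level bin, and a count when it changed by more than 1.5 times. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.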

Results

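The transcriptome of A549 cells was compared 24 hours after transfection with a control siRNA or with an siRNA against p62/SQSTM1, a ubiquitin-binding receptor of selective autophagy that also binds KEAP1, the repressor of the transcription factor NRF2. Each condition was read on 1 array, so all differences below are between 2 arrays and carry no replicate error. The 7896 kept genes had a median log2 level of 6.98 in the siCONTROL array and 7.02 in the siP62 array. Across these genes the levels in both arrays had a Pearson correlation of 0.981; genes are not independent replicates. The median difference between the arrays was 0.04 on the log2 scale, and its robust SD over genes was 0.22. The robust SD ranged from 0.15 to 0.39 over the 20 bins of genes of like level. For 244 genes with more than 1 probe set above the filter, the differences of a gene's probe sets spanned a median of 0.13.

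SQSTM1 mRNA, the target of the siRNA, was lower in the siP62 array. Its log2 value was 8.64 in the siCONTROL array and 7.30 in the siP62 array, a difference of -1.34, which left 39.5% of the control level. This was the third lowest difference of all kept genes, after MIR3190 and HSDL2. The place of MIR3190 rests on 1 of its probe sets (-1.51), as its others differed by -0.92 and -0.42, less than SQSTM1. None of the other 393 genes in its level bin had a lower difference, and the robust SD of that bin was 0.20. The control genes differed less, with 0.13 for GAPDH, 0.19 for TBP, 0.06 for HPRT1, 0.20 for PPIA and -0.08 for B2M. SQSTM1 was read by 1 probe set.

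The comparison of the arrays asked which other transcripts differed when SQSTM1 was silenced. Of the kept genes, 13 were at least 2-fold higher and 18, SQSTM1 and MIR3190 among them, at least 2-fold lower in the siP62 array, together 0.39% of the genes. With the mean over a gene's probe sets 17 were 2-fold lower, without MIR3190, whose probe sets differed unequally. The highest difference was that of SPRR2A, which encodes a precursor of the cornified envelope of squamous epithelium. It had a log2 value of 5.98 in the siP62 array and 4.12 in the siCONTROL array. The latter lay below the filter limit of 5.35 and near the median of all probe sets there, 4.07, so it is not shown to be above background and no fold is given. Its probes were not checked against the near-identical genes of the SPRR2 family. WSB1, a substrate receptor of a ubiquitin ligase, was 2.77-fold higher, from 7.35 to 8.82. ZMPSTE24, the protease that matures prelamin A, was higher by 1.32 on the log2 scale, from 7.82 to 9.14. NPTX1, a neuronal pentraxin, was 2.38-fold higher and CALU, a calcium-binding protein of the secretory pathway, was 2.27-fold higher. Both MET, the receptor of hepatocyte growth factor, and CLDN1, a tight junction claudin, were 2.22-fold higher, MET from 8.92 to 10.07 and CLDN1 from 7.77 to 8.92. The D-type cyclin gene CCND3 was 2.03-fold higher and the Wnt coactivator gene PYGO2 2.06-fold higher. PRRG4, RPL22L1 and ISOC1 were higher by 1.26, 1.24 and 1.19 on the log2 scale. The control values of PRRG4 (4.77), RPL22L1 (4.96) and PYGO2 (5.28) also lay below the filter limit, so the size of their differences is uncertain.

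Among the genes with lower levels in the siP62 array, HSDL2, a hydroxysteroid dehydrogenase-like protein, had the largest difference after MIR3190. Its log2 value was 8.79 in the siCONTROL array and 7.35 in the siP62 array, a 2.71-fold lower level. THOC7, a subunit of the THO mRNA export complex, was 2.28-fold lower. CXCL5, a chemokine that attracts neutrophils, was 2.16-fold lower, with 11.08 in the siCONTROL array and 9.97 in the siP62 array. HAS2, which makes hyaluronan, and REEP5, which shapes the endoplasmic reticulum, were each 2.13-fold lower. SPOP, the substrate adaptor of a cullin ubiquitin ligase, was 2.11-fold lower and DCAF12, a cullin substrate receptor, 2.07-fold lower. CYLD, a deubiquitinase that restrains NF-kB and binds p62, was 2.06-fold lower. The histone methyltransferase gene NSD1 and the ferric reductase gene CYBRD1 were each 2.08-fold lower. The receptor kinase gene ROR1 was 2.06-fold lower and UEVLD 2.16-fold lower. Each of these 12 genes had at most 1 gene of lower difference in its bin of 394 or 395 genes of like level. Since they were chosen for the lowest differences, this rank follows largely from the choice and is no support for them. Without replicates, no difference of a single gene could be tested. The count of genes 2-fold higher depended on the filter, with 25 when no filter was used and 8 at the 70th percentile, and at 1.5-fold the split turned from 164 higher and 126 lower as deposited to 127 and 154 once the median difference was subtracted.

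**Figure D1:**
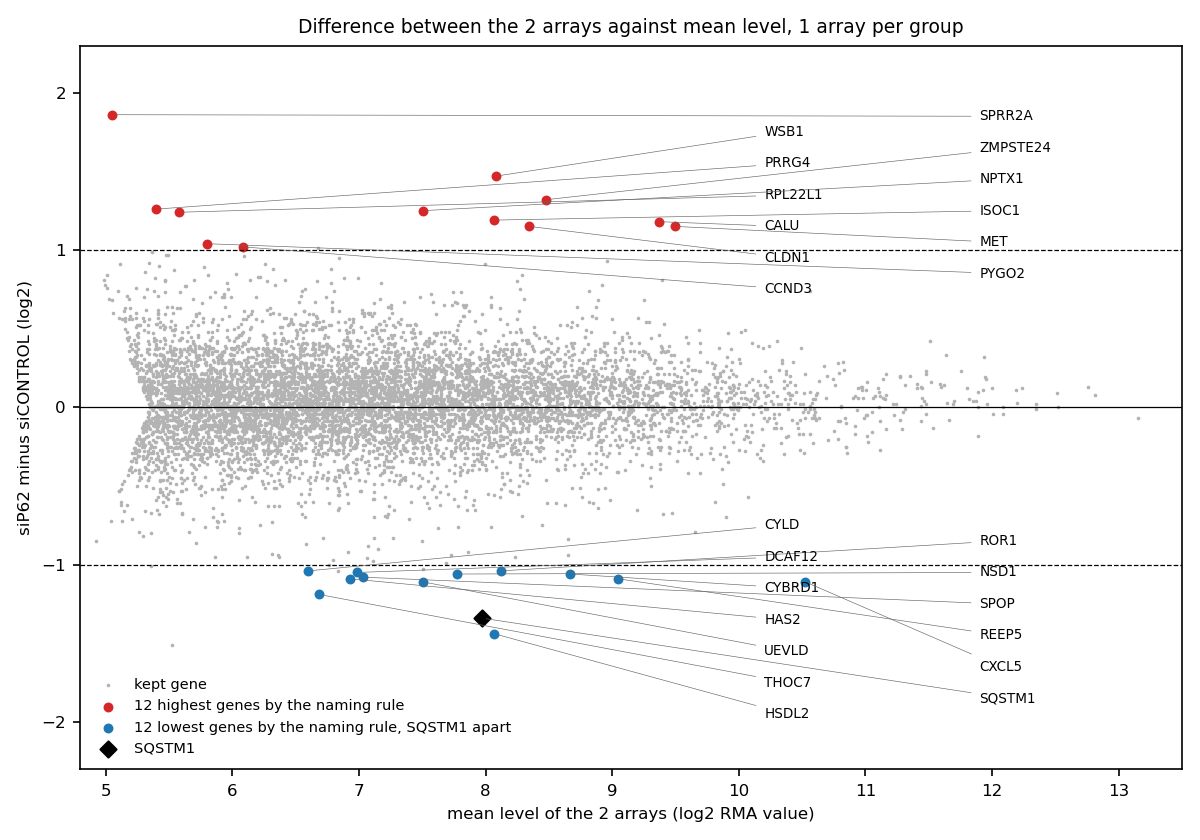
Each grey point is a kept gene, with its mean log2 level over the 2 arrays on the x axis and its difference (siP62 minus siCONTROL, log2) on the y axis; dashed lines mark 2-fold. SQSTM1 (diamond, -1.34) lies among the lowest genes, with the 12 highest (red, with SPRR2A at the top from a control value not shown to be above background) and 12 lowest (blue, HSDL2 at -1.44 the lowest) genes of the naming rule labelled.

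The 40 gene lists asked whether genes of one pathway or cell type differed together. Of the 31 lists with enough kept members, 3 stood apart from random lists of like level, against 1.55 that chance would give, and 28 did not. In 212 of 1000 shufflings of the differences among genes of like level, as many lists or more stood apart, so the number of lists was not beyond chance. Neither the 1.55 nor the shufflings allow for members of a list that vary together between arrays. The medians of 8 lists lay above 0 as deposited and below 0 once the median difference of all kept genes, 0.04, was subtracted, namely autophagy machinery, heat shock, interferon-stimulated, interferon and RNA sensing, oxidative phosphorylation, immediate early, RNA interference machinery, and coronavirus and influenza entry genes.

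NRF2 target genes, which encode antioxidant and detoxification enzymes, were lower in the siP62 array as a list. The median difference of 14 kept members was -0.09, at percentile 1.40 of the random lists, whose central 95% ran from -0.075 to 0.15. With the filter at the 70th percentile it was -0.18 over 11 members, at percentile 0.04. Of the members, 11 were lower, 2 higher and 1 equal, and none differed by 1.5-fold. The largest differences were those of HMOX1, the heme oxygenase (-0.38, from 9.50 to 9.12), TXNRD1, a thioredoxin reductase (-0.36), GSR, the glutathione reductase (-0.29), and KEAP1 (-0.28), which is itself the repressor of NRF2. Of the 35 NRF2 targets fixed, 21 were not named on the array and were not analysed here. Quantile normalization of the columns gave a median of -0.112 at percentile 2.52, inside the random range, or at 2.02, outside it, with another random draw. Leaving out any 1 of 6 members gave a median of -0.08 at percentiles of 2.61 to 3.12, so the list lay close to the limit.

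YAP target genes, which respond to the Hippo pathway, also stood apart on the lower side. The median difference of 10 members was -0.15, at percentile 0.77, with 7 members lower, 2 higher and 1 equal. ANKRD1, a muscle ankyrin repeat protein gene widely used as a YAP readout, was 1.92-fold lower, from 6.83 to 5.89. IGFBP3 differed by -0.36, ARHGEF17 by -0.35 and AMOTL1 by -0.34, while a further probe set of AMOTL1, below the filter limit, differed by 0.19 and the mean of both by -0.08. The list returned inside the random range with the mean over probe sets (median -0.093, percentile 4.33). It also did so with the filter at the 70th percentile (median -0.11, percentile 3.82). When 1 of 5 members was left out, the median was -0.11 at percentiles of up to 4.28.

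Fatty acid synthesis genes stood apart on the higher side, with a median difference of 0.18 over 12 members at percentile 98.23. Of the members, 10 were higher, none of them by 1.5-fold, and 2 were lower. Of the 10, SCD (0.04) and LPIN1 (0.03) were no higher than the median of all kept genes, 0.04. SREBF1, the transcription factor of lipid synthesis, differed by 0.28, INSIG1 by 0.26, and the desaturase FADS2 and elongase ELOVL5 by 0.23 and 0.22. The elongase ELOVL6 (-0.83) and the acetyl-CoA synthetase ACSS2 (-0.28) went the other way, and the mean over the list was 0.055, at percentile 59.65. The median stayed at 0.18 whichever 1 member was left out, at percentiles of 97.09 to 97.93, and for 7 of the 12 members the percentile lay inside the random range. Cholesterol synthesis genes, which share INSIG1 with this list, had a median of 0.125 over 16 members at percentile 91.07, with 12 members higher and 4 lower.

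**Figure D2:**
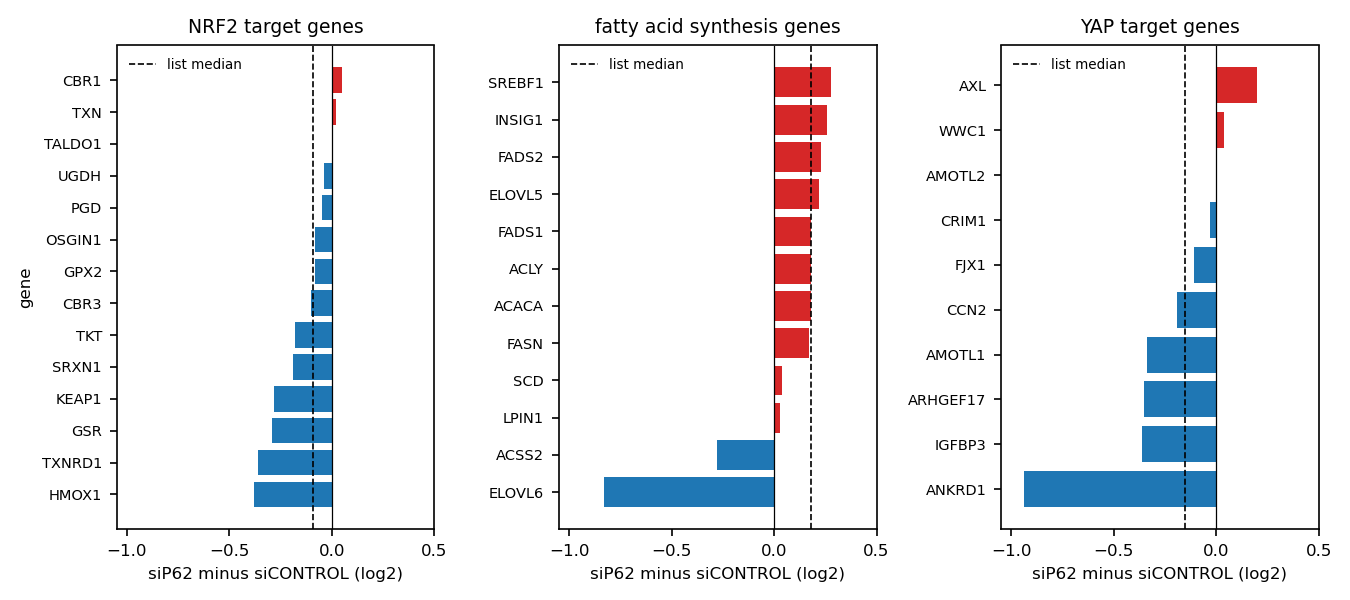
Bars give the difference of each kept member (siP62 minus siCONTROL, log2) in the 3 lists that stood apart, with the list median as a dashed line. Most NRF2 and YAP targets lie below 0 and most fatty acid synthesis genes above 0, with ELOVL6 at -0.83 and ACSS2 at -0.28 as the exceptions.

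Autophagy receptors and p62 partners had a median difference of -0.075 over 16 members, at percentile 2.94 just inside the random range. The list lay at percentile 10.51 (median -0.04) with the filter at the 70th percentile, and at 1.49 with the mean in place of the median, a choice made after the data were seen. CYLD (-1.04) was the only member at least 1.5-fold lower, and the list was not scored without it. Of the 16 members, 9 were lower and 6 higher. Besides CYLD, the largest differences were those of PHB2, a mitophagy receptor (0.35), OPTN, another autophagy receptor (-0.32), and KEAP1. Autophagy machinery genes had a median of 0.015 over 20 members (percentile 31.34) and a mean of -0.006 (percentile 23.30). Lysosome genes had a median of 0.105 over 16 (percentile 85.08). Genes of mTORC1 and nutrient signalling had a median of 0.12 over 17 members (percentile 86.87). Ferroptosis and iron genes lay at -0.10 over 9 members (percentile 2.81), with 5 lower and 4 higher and GPX4, which reduces lipid peroxides, at -0.28. Their median turned to 0.03 over 12 members (percentile 51.33) without a filter and was -0.035 (percentile 12.49) with the filter at the 70th percentile, whereas quantile normalization put the list at percentile 2.20 and loess centring at 2.35.

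NF-kB target genes did not stand apart. Their median was -0.07 over 11 members (percentile 10.60) and their mean 0.012 (percentile 38.95), with 7 lower and 4 higher. Without a filter the median over 16 members was 0.00 (percentile 37.55). PTGS2, the inducible cyclooxygenase, differed by 0.41 and BIRC2, an inhibitor of apoptosis, by 0.33, while the chemokine gene CCL2 and the adhesion molecule gene ICAM1 each differed by -0.25. Interferon-stimulated genes had a median of 0.03 over 13 members (percentile 46.97) and went both ways. SAMD9L was 1.62-fold higher and HERC5 1.47-fold higher, the latter from a control value of 5.06 below the filter limit, whereas ISG20 differed by -0.53 and ISG15 by -0.49. Genes of interferon and RNA sensing pathways lay at 0.03 over 10 members (percentile 44.82). The 3 kept antigen presentation genes had a median of 0.11 and were too few to score. Genes for coronavirus and influenza entry lay at 0.02 over 11 members (percentile 38.20). Genes of the microRNA and RNA interference machinery had a median of 0.01 over 6 members (percentile 36.95) and a mean of -0.118 (percentile 6.53).

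Among the stress responses, amino acid and integrated stress response genes had a median of 0.15 over 14 members (percentile 94.55), with 10 higher and 4 lower. With the filter at the 70th percentile the median was 0.06 over 9 members (percentile 54.67), and the mean over all 14 was 0.078 (percentile 73.34). Of these, PHGDH, the first enzyme of serine synthesis, differed by 0.53, PSAT1 by 0.24 and PSPH, the last enzyme of that pathway, by -0.44. Endoplasmic reticulum unfolded protein response genes had a median of -0.02 over 11 members (percentile 20.36) and a mean of 0.045 (percentile 54.86). Heat shock genes had a median of 0.02 over 9 members (percentile 39.01) and a mean of -0.051 (percentile 13.13). Glutathione and detoxification enzyme genes lay at 0.06 over 12 members (percentile 60.65). The 4 kept metallothionein genes had a median of 0.26 and were too few to score; MT1F was 2.01-fold higher and MT1X differed by 0.29, and probes were not checked against the near-identical members of this family. None of the proteasome subunit genes was named on the array, and they were not analysed here.

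Cell cycle genes did not stand apart. S phase and DNA replication genes had a median of 0.10 over 22 members (percentile 84.16), with CCNE1, the E-type cyclin gene, at 0.55 and MCM10 at -0.42. G2 and mitosis genes had a median of 0.07 over 24 members (percentile 71.17). The p53 target genes lay at -0.02 over 15 members (percentile 20.50) and apoptosis regulator genes at 0.08 over 14 (percentile 70.60). Immediate early genes had a median of 0.005 over 24 members (percentile 25.62) and a mean of -0.053 (percentile 4.84). Secreted senescence-associated genes lay at 0.06 over 13 members (percentile 62.19). Hypoxia and glycolysis genes lay at 0.045 over 16 members (percentile 53.24), oxidative phosphorylation genes at 0.01 over 8 (percentile 34.77) and cytosolic ribosomal protein genes at 0.11 over 19 (percentile 89.87).

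Epithelial genes had a median of 0.07 over 17 members (percentile 69.14), among them CLDN1. Their mean was 0.149, at percentile 97.38, or at 97.66, outside the random range, with the first draw. CLDN1 (1.15) was the only one of them at least 1.5-fold higher, and the list was not scored without it. Mesenchymal transition genes had a median of 0.13 over 9 members (percentile 85.87). TGF-beta target genes had a median of -0.015 over 10 (percentile 22.75) and a mean of 0.013 (percentile 36.93). Hepatocyte and gastric lineage markers lay at 0.05 over 13 members (percentile 57.84) and at -0.01 over all 21 on the array. The markers of other cell types had too few kept members to score. Of 10 alveolar type II and club cell markers on the array, 3 were kept, the surfactant genes SFTPD (-0.58) and SFTPB (-0.36), both with siP62 values below the filter limit, and LPCAT1 (0.14). The median over the 3 was -0.36 and that over all 10 was 0.015. The 3 kept squamous and basal markers, SPRR2A among them, had a median of 0.33, and all 15 on the array one of 0.00. The keratin genes KRT5 and KRT14 of that list lay below the filter, with siP62 values of 2.70 and 4.10. Kept leukocyte markers had a median of -0.06 over 3 of the 13 on the array and of -0.04 over all 13. Fibroblast markers had 0.10 over 3 kept and 0.015 over all 8, and endothelial markers 0.465 over 2 kept and 0.02 over all 13. Neuronal and neuroendocrine markers had 0.265 over 4 kept and 0.07 over all 9.

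**Figure D3:**
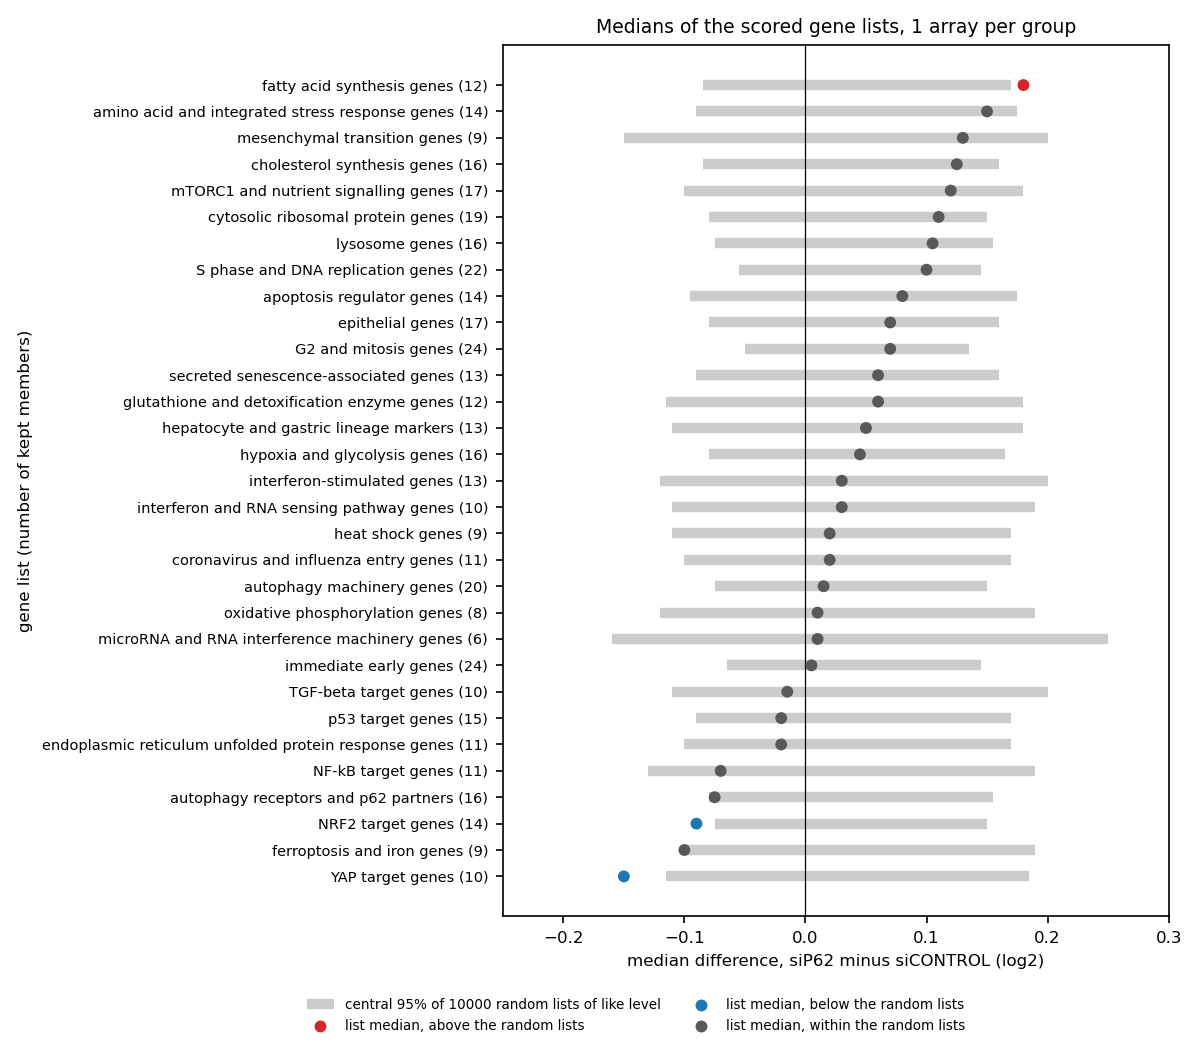
Each point is the median difference (siP62 minus siCONTROL, log2, x axis) of 1 of the 31 scored lists, with the number of kept members in brackets, and each grey bar the central 95% of 10000 random lists of like level. YAP targets (-0.15) and NRF2 targets (-0.09) lie below their bars and fatty acid synthesis genes (0.18) above theirs.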

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

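No test was run on the results in this part, which were looked at after the comparisons were complete. The probe sets without a gene name entered no comparison above. Of the 7380 unnamed probe sets that passed the same filter, 22 were at least 2-fold higher and 16 at least 2-fold lower in the siP62 array than in the siCONTROL array, with a median difference of 0.03. The 22 drew attention as signals above the control array in data that no comparison used. The highest of them, probe set 16877667, had a log2 value of 4.13 in the siCONTROL array and 5.73 in the siP62 array, a difference of 1.60. The lowest, probe set 16685777, had 5.78 and 4.13, a difference of -1.65. In both cases the lower of the 2 values lay below the filter limit, and no gene could be named for either probe set here.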

How the results depend on the processing

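The background of mRNA accessions, the mean and the 5 bins for single lists, and the comparison of both random draws were chosen only after the data were seen. The difference of SQSTM1 kept its sign under the 4 alternatives run on it, between -1.34 and -1.39. The 13 genes at least 2-fold higher became 25 without a filter and 8 with the filter at the 70th percentile, where 14884 and 4859 genes entered in place of 7896. At 1.5-fold in place of 2-fold, 164 genes were higher and 126 lower. The 18 genes at least 2-fold lower numbered 16 to 27 under the other alternatives. Subtracting the median difference kept all 18 and 11 of the 13 higher genes. At 1.5-fold, the share of higher genes went from 56.6% as deposited to 45.2% with the median, 45.8% with the loess curve and 49.5% with quantile normalization, so the direction of that split is not settled. The 3 lists standing apart became 2 with the mean over probe sets and with the filter at the 70th percentile, 4 with the loess curve and with the list mean, and 5 against genes with mRNA accessions; the cause was not tested. The further lists against mRNA accessions were autophagy receptors and p62 partners (percentile 2.38) and ferroptosis and iron genes (1.02). List members without an mRNA accession were left out as well. Ferroptosis and iron genes thus went from 9 members with a median of -0.10 to 8 with one of -0.145. Autophagy receptors and p62 partners kept 16 members and a median of -0.075. With the filter at the 70th percentile the receptor list and the ferroptosis list lay well inside, at 10.51 and 12.49, and without a filter at 3.21 and 51.33. Over lists and alternatives, 299 values stayed on their side of the limits, 6 moved outside and 4 inside. Subtraction of the median cannot change a percentile, and most lists stood apart under no alternative, so this total says little about the 3 lists. Each of the 3 came inside the limits under some alternative, NRF2 targets only with the present draw. The filter also moved medians inside the limits: with it at the 70th percentile, hypoxia and glycolysis genes went from 0.045 to 0.11, interferon-stimulated genes from 0.03 to 0.11 and cholesterol synthesis genes from 0.125 to 0.175 (percentile 97.31), and without it mesenchymal transition genes went from 0.13 to 0.05 and secreted senescence-associated genes from 0.06 to 0.00. The median of TGF-beta targets turned from -0.015 to 0.05 with the mean over probe sets. Between the first and the present draw, 4 calls differed: NRF2 targets under quantile normalization (2.02, then 2.52), ferroptosis and iron genes under loess (2.66, then 2.35) and with the mean (2.54, then 2.48), and epithelial genes with the mean (97.66, then 97.38). Of the genes of the naming rule, AMOTL1 alone moved by more than the spread of genes of like level. This says little for genes read by 1 probe set, SQSTM1 among them, which the mean over probe sets cannot change. MIR3190, outside the naming rule, was not in this comparison. Low signal limits genes with 1 of their values below the filter limit, which were SPRR2A, PRRG4, RPL22L1, PYGO2 and HERC5 in the siCONTROL array and MIR3190, OSTC, ISG20, ICAM1, SFTPB and SFTPD in the siP62 array. No paired analysis was possible because each group held 1 array.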

Other observations

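The tests of the microRNA class were chosen only after its medians were seen. Probe sets at microRNA loci, which on a whole-transcript array read precursor or host transcript rather than the mature microRNA, were lower as a class in the siP62 array. Of 207 kept, 127 were lower and 75 higher, with a median difference of -0.09; 17 were at least 1.5-fold lower and 3 at least 1.5-fold higher. MIR3190, at -1.51 in the probe set that stood for it, was the lowest of all kept genes. That probe set had 6.28 in the siCONTROL array and 4.77, below the filter limit, in the siP62 array. Its other probe sets differed by -0.92 (from 5.69 to 4.77) and -0.42 (from 4.79 to 4.37). It was the only 2-fold gene with more than 1 probe set, and it was no longer 2-fold lower with the mean over probe sets. The 518 other noncoding probe sets had a median of 0.01, also low among random sets of like level (percentile 4.79, central 95% from 0.01 to 0.06), and the 7171 mRNA probe sets one of 0.04. Apart from the genes of the naming rule and MIR3190, the genes past 2-fold were MT1F (1.01), RALGPS2 (-1.04), M6PR (-1.03), the cation-dependent mannose 6-phosphate receptor of lysosomal enzyme sorting, OSTC (-1.01, with a siP62 value of 4.85 below the filter limit) and DDHD2, at 2-fold lower; they were chosen after their values were seen.

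The low level of the microRNA probe sets (median 6.08, against 7.07 for mRNA probe sets) does not account for their median, since it lay at percentile 0.00 of random sets of like level, whose central 95% ran from -0.01 to 0.08. An equal shift of all noncoding probe sets does not account for the whole of it, though a smaller shared shift stays open: the other noncoding probe sets had a median 0.10 above it (0.05 to 0.16 for the central 95% of 10000 resamplings of probe sets). The number of probes per probe set, gene length and variation between arrays stay open, and no biological explanation was tested. A fall of the differences with gene length was noticed in the same look at the data as the microRNA class. It was not analysed here because the build behind the array is not given in the sources used here. Its size is not given, and whether it bears on the list medians was not tested.

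Chance among the lists remains a possible explanation for all 3 lists, as 212 of 1000 shufflings gave as many, with a mean of 1.60 and a highest of 6. The lists lay close to the limits when 1 member was left out. Percentiles were then up to 3.12 for NRF2 targets and 4.28 for YAP targets, and down to 97.09 for fatty acid synthesis genes. By the criterion written before this step, a return inside the limits, 1 member was thus enough to decide each call. Leaving out any 1 of 6 NRF2 targets, 5 YAP targets or 7 fatty acid synthesis genes did so, rather than 1 particular member. The medians were still -0.08 or lower, -0.11 or lower and 0.18. A median can move little when 1 member is left out, so this does not show that the calls are stable. The 3 lists still stood apart against genes with mRNA accessions alone, at 1.43, 0.76 and 98.19, with 13 NRF2 targets in place of 14. These genes were 7171 of the 7896 kept, with the same median difference of 0.04. Noncoding probe sets in the background could thus have moved the percentiles only a little. Variation between any pair of arrays cannot be separated from the effect of the siRNA with 1 array per group. Effects of the siRNA on transcripts other than its target stay open for these lists and for each gene named, since its sequence is not given in the sources used here, and no biological explanation was tested.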
